A study of Mus musculus with 35 samples.

How the data were processed

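H3K4me1, a histone mark of enhancers, was measured by ChIP-seq in murine bone-marrow-derived macrophages. The cells came from wild-type (WT) mice or from mice lacking the type I interferon receptor (Ifnar-KO), IRF1 (Irf1-KO) or IRF3 (Irf3-KO). The labels list 35 samples, of which 7 are inputs without a count table and were not analysed here. The deposited tables, 8 in number, hold raw read counts per region, whole numbers that were not normalised by the authors as far as the values show. Per the submitters' processing notes, Bowtie2, Picard, MACS2, MACS3 and deepTools were used with the mm10 build; their versions, their order, and how regions were merged and counted are not stated.

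The tables of LPS-treated cells of all 4 genotypes and of the LPS time course share 1 set of 95198 regions. Both IFNγ tables share another set of 105583 regions. The IFNβ table has its own 112410 regions and a single library. Total counts ranged from 2.84 to 48.1 M (1e6 counts) over the 32 columns of the tables. The 8 h library of the time course held the same counts as WT LPS replicate 3 in 95198 of 95198 regions and was used only within the course. The WT unstimulated library 1 of the IFNγ table equalled library 2 of the LPS table in 5049 of 5049 regions with equal coordinates. The same held for the Irf1-KO unstimulated libraries, again 5049 of 5049. The tables therefore hold 4 distinct WT and 3 distinct Irf1-KO unstimulated libraries, where the labels list 3 and 2.

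Each response was tested within 1 table in R 4.3.3 with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16, robust fit, TMM factors, filterByExpr with a minimum count of 10). Regions at an adjusted p under 0.05 were called gained or lost. The difference between a KO and WT was tested as the genotype by stimulus interaction over all libraries of both genotypes on the same regions. Responses are called smaller or larger in the KO by the sign of the log2 change in the KO minus that in WT. A loss in WT that is weaker in the KO therefore counts as larger. Every adjusted p for a region comes from these fits unless another tool is named. Gene lists were tested over their assigned regions with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Its p-values were adjusted over 96 tests of 12 lists in 8 comparisons. The labels do not state that replicates are separate animals, so each p measures the spread between these samples.

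Groups with 1 library got no test. Their log2 ratios of TMM-scaled counts per 1e6 (CPM) used a prior count of 2. Medians of region sets were set beside 10000 random sets of regions matched on mean count, as a description of these libraries. The IFNβ table holds no unstimulated library. Its regions were therefore matched to the LPS set 1 to 1 by a reciprocal overlap of at least 50%, compared per base with the mean of the WT unstimulated libraries of the LPS table, and centred on the median of all matched regions. Regions with at least 20 counts and a log2 ratio of at least 1 were counted as gained there. Regions of the LPS and IFNγ sets were matched in the same way. The correlation of log2 changes that a shared unstimulated library alone can give was approached in 20 simulations. They shared the relative error of that library but drew its counting error separately for each set, so they can understate this correlation.

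The reference gene table covers mm10 but gives gene bodies without strand, exons or introns. Each region was therefore assigned to the protein-coding gene body it overlaps, or to the nearest one within 100 kb for gene lists, in place of the planned distance to transcription start sites. Gene names are positions on the genome and no measure of expression. Planned motif tests were not run because no genome sequence was used here. Coordinates are 1-based mm10 positions.

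The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Per tested response, the rule names the 10 gained and 5 lost regions with the largest fitted change among those with separated groups and a mean of at least 1 CPM. It adds the region with the smallest p of up to 8 genes per list. In groups with 1 library it names the 5 regions with the highest ratio and at least 50 counts, and the regions named for WT LPS. The lists were type I interferon-stimulated genes (27 genes in the annotation), IFNγ and IRF1 targets (29), NF-κB and inflammatory genes (31), macrophage identity genes (25), cholesterol and lipid genes (15) and housekeeping genes (15). Markers of neutrophils (11), T cells (9), B cells (8), dendritic cells (7), stroma (8) and erythroid cells (5) completed them. For a region with 1 to 3 counts in a group, the text gives the ratio with its exact 95% Poisson interval. Intervals cover counting error only.

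The fits were tested on simulated data with 100 regions changed by 2-fold and 100 by 4-fold. In the simulated WT LPS design with 94084 regions, 77% and 100% were recovered, with 13 false calls. In the Ifnar-KO LPS design with 89577 regions the shares were 42% and 96%, with 5 false calls. In the Irf1-KO LPS design with 89638 regions they were 38% and 94%, with 13 false calls. In the WT IFNγ design with 102300 regions they were 66% and 99%, with 4 false calls. In the Irf1-KO IFNγ design with 98476 regions they were 64% and 100%, with 4 false calls. The interaction tests recovered 27% and 82% for Ifnar-KO LPS among 95098 regions, 35% and 81% for Irf1-KO LPS among 95150 regions, and 34% and 90% for Irf1-KO IFNγ among 103958 regions.

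Alternatives covered DESeq2 1.42.0 (Wald test, and its size factors in edgeR), total counts without TMM, a loess offset, no count filter, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. Others were a prior count of 5, a minimum of 50 counts, and 20 kb in place of 100 kb for gene assignment. An overlap of 1 bp, subsets by the change in each KO, LPS against IFNγ without the shared library, IFNβ against unstimulated library 3 alone, camera with an estimated correlation, and leaving out KO libraries for the medians of WT-gained regions were added after seeing the data. Region overlaps used GenomicRanges 1.54.1. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9.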

Results

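H3K4me1 was profiled in bone-marrow-derived macrophages, unstimulated or after 8 h with LPS (100 ng/mL), a bacterial cell-wall product sensed by TLR signalling, or with the interferons IFNβ or IFNγ (100 ng/mL). Unstimulated WT cells and LPS-treated WT cells had 3 libraries each, WT cells with IFNγ had 2, and WT cells with IFNβ (1 U/mL) had 1. Ifnar-KO cells had 2 unstimulated and 2 LPS libraries. Irf1-KO cells had 2 LPS libraries and 2 IFNγ libraries, with 2 unstimulated libraries in each table. Irf3-KO cells had 1 unstimulated library, 1 with LPS, and 1 with LPS and IFNβ (10 U/mL). A time course gave WT cells LPS for 8 h and followed them after wash-out to 24, 48, 72 and 96 h and 6 days, with 1 library per time. The label of the 72 h library states a wash of 66 h after the 8 h of LPS. Regions were named by the gene body they overlap or the nearest one. Distances are given for some regions only, so a gene named without one need not be overlapped.

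Total counts in regions were 3.82, 15.7 and 31.1 M (M, 1e6 counts) in unstimulated WT libraries 1 to 3 and 6.54, 13.4 and 29.0 M in the LPS libraries. The IFNγ table held 15.9 and 12.1 M in unstimulated WT libraries and 14.8 and 14.0 M after IFNγ. Ifnar-KO libraries held 4.10 and 13.9 M unstimulated and 5.69 and 13.8 M with LPS. Irf1-KO libraries of the LPS table held 2.84 and 14.5 M unstimulated and 3.15 and 14.9 M with LPS. Those of the IFNγ table held 14.6 and 11.7 M unstimulated and 14.4 and 13.1 M with IFNγ. Irf3-KO libraries held 16.7, 11.9 and 16.8 M, the IFNβ library 13.1 M, and the course libraries 29.0, 48.1, 29.0, 12.6, 10.6 and 8.40 M in order of time.

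Regions over the deleted genes kept their signal in the KO cells. The region over Irf1 (11:53771062-53787728) had 72 ± 1.90 CPM (SD, n = 3) in unstimulated WT cells, 87.2 ± 9.04 (n = 2) in unstimulated Irf1-KO cells and 75.8 ± 2.09 (n = 2) in Irf1-KO cells with LPS. In the IFNγ table the Irf1 region at 11:53771062-53780741 had 33.5 ± 1.71 CPM in WT and 41.3 ± 0.00849 CPM in Irf1-KO cells (n = 2 each), and 19.3 ± 4.17 and 18.9 ± 3.52 CPM with IFNγ. The region over Ifnar1 (16:91486060-91490992) had 22.5 ± 0.596 CPM (n = 3) in WT, 27.4 ± 0.392 CPM in Ifnar-KO and 26.1 ± 0.542 CPM in Ifnar-KO cells with LPS (n = 2 each). The region over Irf3 (7:44998415-45002776) had 11.3 ± 0.656 CPM (n = 3) in WT cells and 10.6, 12.3 and 10.7 CPM in the Irf3-KO libraries without stimulus, with LPS, and with LPS and IFNβ. The tables count broad regions and not exons, and the labels do not place the deletions, so these values check nothing about the genotypes.

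LPS raised H3K4me1 in WT macrophages at regions of inflammatory and interferon-stimulated genes. The region with the smallest p among named genes lay over Nfkb1, an NF-κB subunit gene, at 3:135634551-135641955 and went from 6.15 ± 0.10 to 34.0 ± 0.99 CPM (SD, n = 3 each), a log2 change of 2.46 (SE 0.13, adjusted p = 4.19e-12). Among interferon-stimulated genes, Ifit1, an antiviral RNA-binding protein, gained 3.21 (SE 0.22, adjusted p = 1.25e-10). A region at Gbp2, a guanylate-binding protein gene, gained 2.22 (SE 0.14, adjusted p = 3.16e-11). In total 7166 of 94084 regions were gained and 526 were lost, with a median log2 change of 1.16 in gained and -0.45 in lost regions.

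Among regions with separated groups and a mean of at least 1 CPM, the largest gains in WT cells lay over or near Ntng2, a membrane-bound netrin (2:29216658-29218028), with a log2 change of 5.47 (SE 0.62, adjusted p = 1.93e-06; 0.12 ± 0.13 to 3.78 ± 2.37 CPM), and Atrnl1 with 4.69 (SE 0.57). Nat10, an RNA acetyltransferase (2:103721231-103722544), followed with 4.43 (SE 0.35, adjusted p = 2.12e-09), and Hdc, the histamine-forming enzyme (2:126613061-126615440), with 4.32 (SE 0.34, adjusted p = 1.3e-09). Fam124b gained 4.37, Zfp780b 4.36, Nhsl2 4.27, Mroh8 4.26 and Tmprss2 4.24. The region nearest to Acsl1, an acyl-CoA synthetase, lay 63298 bp away and gained 4.11. Losses were smaller in size and number. The largest was a region within Gbp5 (3:142497593-142499544) that dropped from 7.06 ± 1.90 to 0.65 ± 0.67 CPM, a log2 change of -4.10 (SE 0.37, adjusted p = 3.33e-08). A neighbouring Gbp5 region (3:142500468-142502475) gained 3.28 (SE 0.26). Further losses lay near Gm1966 (-2.97, 68363 bp away) and at Vcpip1 (-2.35), Gm6034 (-2.33) and Cpeb4 (-2.26).

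Of 99 regions at type I interferon-stimulated genes, 48 rose and 2 fell in WT cells with LPS, and 63 and 3 when adjusted over the list alone. They lay at 20 of 26 genes, among them Zbp1, a sensor of unusual nucleic acids (3.07), Oasl2 (3.42), Cmpk2 (2.74), Usp18, a brake on interferon signalling (2.42), Trim30a (1.91) and Parp14 (1.71). Of 124 regions at IFNγ and IRF1 targets, 58 rose and 2 fell, and 67 and 4 when adjusted over the list alone. These included Iigp1, an immunity-related GTPase (3.48), Gbp7 (1.90), Gbp3 (1.85), Gbp4 (1.21), Nos2, the inducible nitric oxide synthase (1.51, 30071 bp away), and a region 39253 bp from Irf1 (1.16). Of 171 regions at NF-κB and inflammatory genes, 83 rose and 4 fell, and 87 and 5 when adjusted over the list alone. Examples were Ptgs2, the inducible prostaglandin synthase (2.79, 92737 bp away), Il6 (2.21, 91752 bp away), Il10 (2.05, 18744 bp away), Tnfaip3, a brake on NF-κB (1.80, 64737 bp away), Nfkbiz (1.67, 31773 bp away), Cd40 (1.24) and Saa3 (0.93). By camera the median log2 changes of 0.65, 0.45 and 0.46 in these lists gave adjusted p = 1.74e-28, 7.95e-27 and 3.84e-30. With an estimated correlation none of the lists passed, at adjusted p = 0.459, 0.423 and 0.459 with an estimated correlation.

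Macrophage identity genes moved both ways, with 18 of 198 regions gained and 7 lost, and 23 and 8 when adjusted over the list alone. Cebpb (1.91, 40565 bp away), Lpl, lipoprotein lipase (1.58, 15724 bp away), Itgam (1.41), Adgre1, which encodes the F4/80 antigen (1.12), Mitf (0.94) and Fcgr1 (0.76) gained signal. Mrc1, the mannose receptor, changed by -0.56 (SE 0.10, adjusted p = 0.00037) and Cebpa by -0.63. The list's median was 0.01 while its camera test pointed down (adjusted p = 0.922). Of 113 regions at cholesterol and lipid genes, 6 rose and 2 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.217). Ch25h gained 1.27, Scd1 0.94 and Abcg1 0.45. Hmgcs1 (-0.60) and Insig1 (-0.59), both of the sterol pathway, lost signal, and Scd2 at 0.27 (adjusted p = 0.111) did not pass. Of 64 regions at housekeeping genes, 6 rose and 1 fell, and 6 and 2 when adjusted over the list alone (camera adjusted p = 0.617). Ywhaz gained 0.85 and Actb changed by -1.09, while Gapdh at 0.24 (adjusted p = 0.328) did not pass.

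Markers of other cell types moved in part with LPS in WT cells, where 7.62% of all regions were gained. Of 20 neutrophil regions 1 rose (Camp, 1.33), and of 22 T cell regions 1 rose (Cd3e, 1.84). Of 22 B cell regions 4 rose (18.2%), among them Blk (1.82), Ebf1 (1.41) and Pax5 (1.13). Of 40 dendritic cell regions 7 rose (17.5%), among them Ccr7 (0.96), Zbtb46 (0.88) and Flt3 (0.81), and the list's camera test gave adjusted p = 0.0073, and adjusted p = 0.677 with an estimated correlation. Of 51 stroma regions 6 rose (11.8%), near Dcn (3.07, 37361 bp away) and Runx2 (0.99, 35283 bp away), and 0 of 39 when only regions within 20 kb were taken, while the 4 erythroid regions, at Klf1, Epor, Hba-a1 and Gata1, had adjusted p from 0.627 to 0.841. After IFNγ 3 of 49 dendritic cell regions and 2 of 52 stroma regions rose, both near Runx2, and 0 of 41 stroma regions within 20 kb.

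The numbers of LPS-gained and lost regions depended on single libraries. Without unstimulated library 3 the WT gains numbered 4690 and the losses 160, and without unstimulated library 2 the losses numbered 1.4e+02. With DESeq2 249 regions were lost, with total counts 816, and a 2-fold minimum left 4180 gains and 35 losses. The unstimulated and LPS libraries of the same number resembled each other, with correlations of their deviations from the group means of 0.25, 0.31 and 0.31 in 85255 regions against at most -0.09 for other pairs. With the replicate number as a block, 10817 regions were gained and 3770 lost, and all 7166 gained regions were among those gained with the block.

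**Figure D1:**
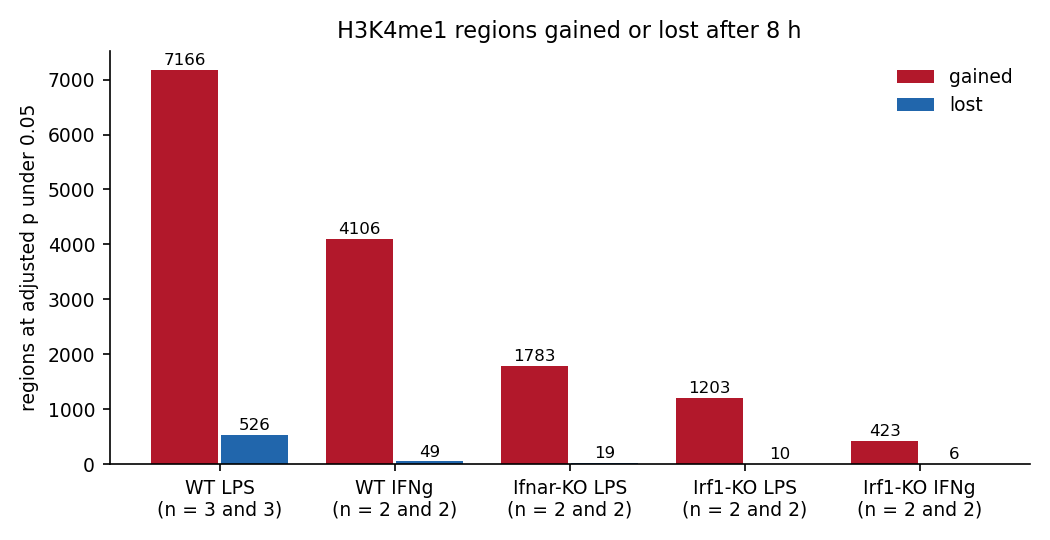
Number of H3K4me1 regions gained (red bars) or lost (blue bars) at an adjusted p under 0.05 after 8 h of stimulation, with the numbers of stimulated and unstimulated libraries under each comparison. Gains outnumber losses in each, from 7166 against 526 in WT cells with LPS to 423 against 6 in Irf1-KO cells with IFNγ.

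IFNγ in WT cells raised H3K4me1 at 51 of 129 regions of IFNγ and IRF1 targets, among others. A region near Gbp6 (5:105261966-105264622) gained 4.67 on the log2 scale (SE 0.28, adjusted p = 6.46e-12, n = 2 and 2). Gbp3 gained 2.74 (SE 0.18), Gbp2 2.25 (SE 0.15) and Gbp5 3.31 (SE 0.25). Nat10 gained 4.95 (SE 0.30, adjusted p = 6.46e-12), a region 54625 bp from Usp38 gained 4.83 (SE 0.42), and a region 16473 bp from Iigp1 gained 4.76 (SE 0.42). In total 4106 of 102300 regions were gained, with a median log2 change of 1.48, and 49 were lost, with a median of -0.66.

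Several large gains rose from 1 to 3 unstimulated counts. Pdpr went from 3 to 187 counts, a ratio of 60.4 (95% interval 20.3 to 295.0), Bbs5 from 3 to 128 (41.3, 13.8 to 203.0) and Clpb, a mitochondrial chaperone, from 3 to 109 (35.2, 11.7 to 173.0). Gm5142 had a ratio of 59.1 (10.2 to 2370.0), Atrnl1 34.4 (9.17 to 289.0) and Nr1h5 28.6 (7.57 to 241.0). The largest losses lay at Gbp5 (3:142497624-142499613; -4.29, SE 0.35, adjusted p = 1.3e-09), 68362 bp from Gm1966 (-2.99), and at Tgtp2, an interferon-inducible GTPase (-2.91, SE 0.29, adjusted p = 3.49e-08), Vcpip1 (-2.23) and Zyx, a focal adhesion protein (-1.43, SE 0.14).

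Of 129 regions at IFNγ and IRF1 targets, 51 rose and 6 fell with IFNγ in WT cells, and 58 and 8 when adjusted over the list alone. They lay at 24 of 28 genes, among them Iigp1 within its gene body (2.57), Gbp7 (1.67), Socs1, a feedback inhibitor of cytokine signalling (1.64), and Nos2 (1.46). Of 93 regions at type I interferon-stimulated genes, 17 rose and 1 fell, and 24 and 1 when adjusted over the list alone. Oasl2 gained 3.54, Usp18 2.89, Zbp1 2.89, Ifit2 2.22, Ifit1 1.81 and Cmpk2 1.34, and Ifi204 changed by -1.03 (SE 0.20, adjusted p = 0.00138). Of 191 regions at NF-κB and inflammatory genes, 22 rose and 3 fell, and 36 and 4 when adjusted over the list alone. Ptgs2 gained 2.24, Il10 1.43, Bcl3 1.03, a region 25884 bp from Nfkb1 0.97, Tnfaip3 0.95 and Ccl5 0.84, while Acod1, which makes itaconate (-0.86), and Nfkbia, an inhibitor of NF-κB (-0.79), lost signal. Camera gave adjusted p = 1.24e-38, 1.73e-09 and 0.00164 for these lists, and adjusted p = 0.423, 0.494 and 0.677 with an estimated correlation.

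Among 223 regions at macrophage identity genes 6 rose after IFNγ, among them Lpl (2.51), Itgam (1.34) and Mertk, a receptor for dying cells (1.03). Adgre1 at 1.10 (adjusted p = 0.0774) and Mrc1 at -0.36 (adjusted p = 0.12) did not pass. Among 125 cholesterol and lipid regions 3 rose, with Abcg1, a cholesterol exporter, at 1.44, while Hmgcs1 at -0.43 (adjusted p = 0.0751) did not pass. Among 71 housekeeping regions 1 rose, and Actb at -0.71 (adjusted p = 0.164) did not pass. Without unstimulated library 2 the gains numbered 2648 and the losses 26, and without IFNγ library 1 or 2 the losses numbered 108 or 267. DESeq2 gave 1985 gains and 15 losses, a 2-fold minimum left 8 losses, and a loess offset gave 77. With the replicate number as a block, 8289 regions were gained and 2416 lost.

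LPS and IFNγ raised many of the same regions in WT cells. Gbp2 gained 2.22 with LPS and 2.25 with IFNγ, and Usp18 gained 2.42 and 2.89. Parp14 gained 1.71 with LPS and had 0.54 with IFNγ (adjusted p = 0.296), and Camp gained 1.33 with LPS and had 0.27 with IFNγ (adjusted p = 0.815); the difference between stimuli was not tested. Of 80210 matched regions, 4124 were gained with LPS, 2439 with IFNγ and 1614 with both, where independence gives 125.4. Both stimuli lowered 17 regions, where independence gives 0.287. They lay over or near Gbp5, Gm1966, Vcpip1, Gm6034, Tgtp2, Ifi204, Acod1, Nfkbia, Patl2, Parp12, Slfn2, Etv3, Tdp1, Samhd1, Jade1, Eya1 and Zyx, with the Gm1966 region 68363 bp and the Jade1 region 177475 bp away. Across regions, which are not independent replicates, the log2 changes had r = 0.684 and rho = 0.497. Unchanged groups simulated around the shared unstimulated library gave r = 0.0809. The simulation drew the counting error of the shared library separately for each stimulus, so 0.0809 can understate what that library alone gives. Without that library in the LPS fit, 1364 regions were gained with both (84.7 with independence) and r was 0.613.

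Without the type I interferon receptor, LPS still raised regions at Nfkb1 and other NF-κB genes. Nfkb1 gained 2.48 in Ifnar-KO cells (SE 0.19, adjusted p = 3.58e-05, n = 2 and 2), Tnfaip3 1.80 and Ptgs2 2.60, beside 2.46, 1.80 and 2.79 in WT cells. Other WT-gained regions varied. The Iigp1 region had 0.06 in Ifnar-KO cells beside 3.48 in WT, Usp18 0.36 beside 2.42 and Nat10 0.72 beside 4.43, while Ifit1 gained 2.10 (SE 0.38, adjusted p = 0.00757) beside 3.21. Without a replicate block the tests of these differences did not pass, at adjusted p = 0.493 for Iigp1, 0.244 for Usp18 and 0.456 for Nat10. With the replicate number as a block all 3 passed, among 206 regions with a lower log2 change in the KO than in WT and 41 with a higher one. In total 1783 of 89577 regions were gained, with a median log2 change of 1.66, and 19 were lost, with a median of -0.62.

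Large gains in Ifnar-KO cells included P4htm, a prolyl hydroxylase (4.14, SE 0.44, adjusted p = 0.000211; 3.17 in WT). Others started from 1 to 3 counts: Kcna2 with a ratio of 41.5 (95% interval 7.08 to 1670.0), Lcp2, an adaptor of immune receptors, with 26.7 (7.08 to 226.0), Parvb with 22.4 (7.38 to 111.0) and Ptges, a prostaglandin E synthase, with 18.4 (6.02 to 91.9). Losses lay at Cpeb4 (-2.54, adjusted p = 0.0371), Bcl2a1b (-1.39), Nfkbia (-1.17, SE 0.16, adjusted p = 0.00108) and 254741 bp from Dusp4 (-0.97). Of 166 regions at NF-κB and inflammatory genes, 41 rose and 2 fell, and 67 and 3 when adjusted over the list alone. Il6 gained 2.72 (76501 bp away), Cd40 1.15, Saa3 1.09, Ccl5 1.08 and Traf1 1.03. Of 118 regions at IFNγ and IRF1 targets, 16 rose, and 20 when adjusted over the list alone. Gbp5 gained 3.03 (SE 0.38), Gbp6 1.69, Gbp3 1.56, Gbp7 1.33, Gbp2 1.23, Nos2 1.22, a region assigned to Irf1 but not over it 0.95 and Ciita, the regulator of MHC class II, 0.76. Of 86 regions at type I interferon-stimulated genes, 9 rose, and 16 when adjusted over the list alone. Oasl2 gained 2.45, Trim30a 2.43, Parp14 1.43, Oasl1 0.63 and Rsad2 0.62. Camera gave adjusted p = 1.25e-28, 4.83e-08 and 4.64e-07 for these lists, and adjusted p = 0.494, 0.584 and 0.677 with an estimated correlation. Mitf gained 1.26 and Mrc1 changed by -0.77 (adjusted p = 0.049).

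Without the block, the response itself differed from WT at 3 regions of 95098. A region 137288 bp from Slco3a1, an organic anion transporter (7:74692068-74699280), gained 2.38 in WT and had 0.58 in Ifnar-KO cells (difference -1.79, SE 0.25, adjusted p = 0.0156; counts 422 to 2016 in WT and 133 to 224 in the KO). A region 30211 bp from Poc1b gained 2.70 in WT and had -0.04 in the KO (difference -2.75, SE 0.44, adjusted p = 0.0489). A region at Rsad2, an antiviral enzyme (12:26443595-26445852), had -1.73 in WT and 0.49 in the KO (difference 2.22, SE 0.32, adjusted p = 0.0156). Over all 7166 WT-gained regions the median difference was -0.25, and 72% were negative, in part because they were chosen by their gain in the WT libraries. The list of type I interferon-stimulated genes had a median difference of -0.35 (camera adjusted p = 1.21e-09, and adjusted p = 0.494 with an estimated correlation), with 8 of 99 regions smaller and 2 larger when adjusted over the list alone. IFNγ and IRF1 targets had -0.20 (camera adjusted p = 3.89e-08, and adjusted p = 0.459 with an estimated correlation), with 12 of 124 smaller and 2 larger when adjusted over the list alone, and NF-κB genes had -0.002 (adjusted p = 0.916).

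Of the WT-gained regions, 6520 were in the Ifnar-KO fit, with a median of 0.80 there beside 1.07 in WT for the same regions. Of these, 1686 were called gained in the KO (25.9%). Regions called from WT libraries 1 and 2 alone (3243) had medians of 1.48 in WT library 3 and of 0.72 and 1.14 in the Ifnar-KO pairs. The gains numbered 870 without the second unstimulated Ifnar-KO library and 3009 without the other one, 746 with DESeq2 and 6291 with the replicate block. Leaving out any of the 4 Ifnar-KO libraries or WT unstimulated library 3 ended both calls of a smaller response, leaving out WT unstimulated library 1 or 2 or WT LPS library 2 left 1, and the losses moved between 69 and 116. The call of the larger response at 1 region became 0 without WT unstimulated library 2 or 3 or any Ifnar-KO library, 8 without WT LPS library 1 and 2 without WT LPS library 2.

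**Figure D2:**
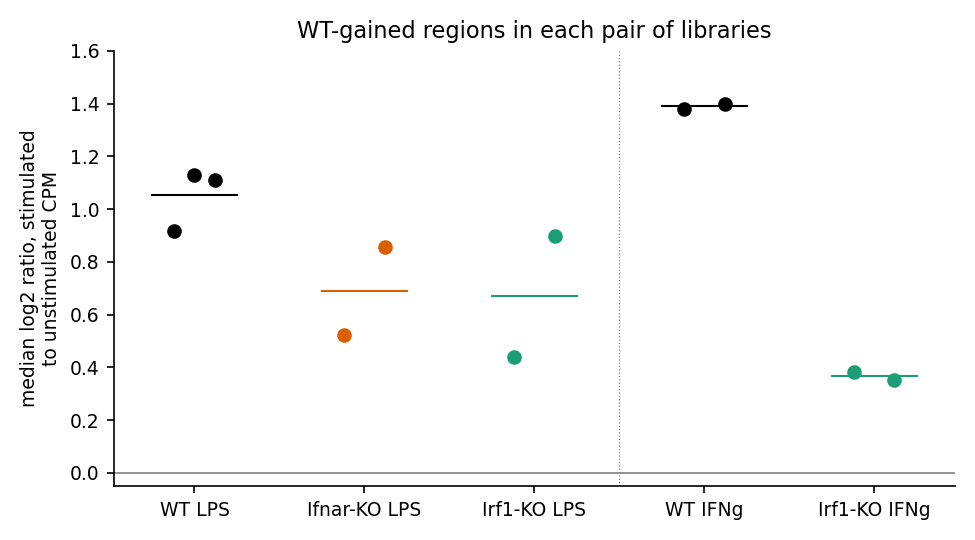
Median log2 ratio of stimulated to unstimulated CPM over the regions gained in WT cells (7166 for LPS, 4106 for IFNγ) in each pair of libraries of the same number; points are pairs and lines their means. Irf1-KO pairs with IFNγ sit at 0.38 and 0.35, below the WT pairs at 1.38 and 1.40, while the KO pairs with LPS range from 0.44 to 0.90 beside 0.92 to 1.13 in WT.

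LPS raised H3K4me1 in Irf1-KO cells at some regions of interferon-stimulated and inflammatory genes too. Hdc gained 4.65 (SE 0.49, adjusted p = 9.06e-05, n = 2 and 2), Il20rb, a cytokine receptor chain, 4.16 (SE 0.41, adjusted p = 6.39e-05), Siah3 4.03 and a region near Spocd1 4.02 (SE 0.41). Ifit1 gained 2.65 beside 3.21 in WT and Nfkb1 2.12 (SE 0.28) beside 2.46. Nat10 at 2.45 did not pass (adjusted p = 0.0501). In total 1203 of 89638 regions were gained, with a median log2 change of 1.72, and 10 were lost, with a median of -1.11.

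Other large gains in Irf1-KO cells with LPS had few unstimulated counts, among them Zfp362 with a ratio of 46.0 (95% interval 7.88 to 1860.0), Slc22a5, a carnitine transporter, with 18.9 (6.15 to 94.1) and a region 182401 bp from Edn1, endothelin, with 19.8 (6.47 to 98.7). The region within Gbp5 that fell in WT cells also fell here (-3.45, SE 0.58, adjusted p = 0.00259), as did the region 68363 bp from Gm1966 (-3.54), Gm6034 (-2.27), Vcpip1 (-1.76) and Ccnl1 (-1.16). Of 91 regions at type I interferon-stimulated genes, 11 rose, and 32 rose and 1 fell when adjusted over the list alone. Zbp1 gained 2.53, Cmpk2 2.29, Ifit2 1.77, Parp14 1.62, Ifit3 1.11 and Oasl1 0.68. Of 121 regions at IFNγ and IRF1 targets, 13 rose and 1 fell, and 18 and 2 when adjusted over the list alone. Gbp5 gained 2.92, Ciita 1.62, Gbp2 1.56, Nos2 1.47, Gbp7 1.39, Tgtp1 1.38, Tap1, a peptide transporter, 1.24 and a region assigned to Irf1 but not over it 0.87. The region over Irf1 itself had 87.2 CPM in unstimulated Irf1-KO cells and 75.8 CPM with LPS. Of 165 regions at NF-κB and inflammatory genes, 29 rose, and 54 rose and 1 fell when adjusted over the list alone. Ptgs2 gained 2.32, Il6 2.30, Il10 2.22, Tnfaip3 1.74, Nfkbiz 1.47, Ccl5 1.05 and Traf1 0.90. Camera gave adjusted p = 5.47e-21, 2.06e-08 and 9.02e-24 for these lists, and adjusted p = 0.677, 0.722 and 0.459 with an estimated correlation. Cebpb gained 3.11 (SE 0.50) and Scd1 1.69. Of 37 dendritic cell regions 3 rose, all at Ccr7 (1.08 at the smallest p), or 8.1% beside 1.34% of all regions (camera adjusted p = 0.00153, and adjusted p = 0.695 with an estimated correlation). Of 21 B cell regions 2 rose (9.5%), at Blk (2.22) and Ebf1 (2.24).

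By edgeR's interaction test no region differed between Irf1-KO and WT cells in its response to LPS (0 smaller and 0 larger of 95150), with 1547 regions at an unadjusted p under 0.05. With the replicate number as a block, 87 regions were smaller and 1 larger, among them Rnaseh2b (difference -1.61; 1.96 in WT and 0.30 in the KO), Myo1e, a myosin (-2.17), and Pcp4 (-2.75; 3.36 and 0.46). IFNγ and IRF1 targets had a median difference of -0.14 (camera adjusted p = 1.09e-06, and adjusted p = 0.494 with an estimated correlation), with 0 regions passing when adjusted over the list alone. The Irf1-KO median of 6579 WT-gained regions was 0.80 beside 1.08 in WT, and 1176 were called gained (17.9%). Irf1-KO and Ifnar-KO cells did not differ at any of 93582 regions by edgeR's test (0 and 0, with 1242 at an unadjusted p under 0.05, and 8 smaller and 8 larger with the block). The gains fell to 143 without the second unstimulated library and to 526 without the second LPS library, rose to 1901 and 2007 without the first of each, and numbered 279 with DESeq2 and 5455 with the block. Without the second unstimulated Irf1-KO library 10 regions were smaller than in WT and 2 were lost, without the first LPS library 4 were smaller and 80 lost, without the second LPS library 31 were lost, and without WT unstimulated library 1 1 region was smaller.

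**Figure D3:**
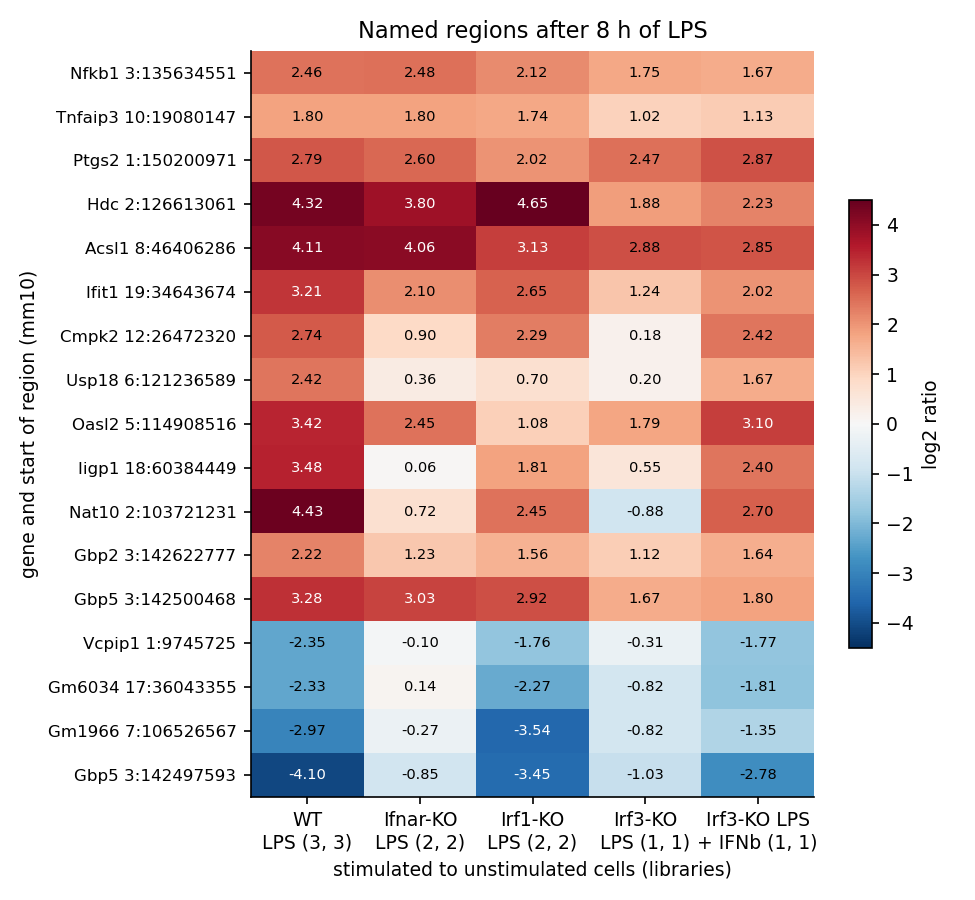
Log2 ratio of stimulated to unstimulated H3K4me1 at named regions (rows, with gene and start position) in WT, Ifnar-KO, Irf1-KO and Irf3-KO cells with LPS and in Irf3-KO cells with LPS and IFNβ (columns, with numbers of stimulated and unstimulated libraries); red is higher and blue lower after stimulation. Nfkb1 ranges from 1.67 to 2.48, while Nat10 and Iigp1 have 0.72 and 0.06 in Ifnar-KO cells beside 4.43 and 3.48 in WT.

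After IFNγ, regions that gained H3K4me1 in WT cells gained less in Irf1-KO cells. A region of Nid1, a basement-membrane protein (13:13489926-13493302), gained 4.07 in WT and had -0.03 in Irf1-KO cells, a difference of -4.11 (SE 0.44, adjusted p = 0.00296; counts 28 to 487 in WT and 43 to 44 in the KO, n = 2 each). Il23r, a cytokine receptor subunit, gained 3.72 in WT and had 0.50 in the KO (difference -3.23, adjusted p = 0.00578), and Ncoa7 2.21 and -0.66 (difference -2.87, adjusted p = 0.00464). Usp18 differed by -2.60 (adjusted p = 0.0133; 2.89 and 0.30) and Gbp2 by -1.21 (adjusted p = 0.0461; 2.25 and 1.05). Of 103958 regions, 125 were smaller in the KO and 3 larger, and 1386 and 142 with the replicate number as a block.

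Other smaller responses in Irf1-KO cells with IFNγ lay at Mroh8 (-3.64; 3.13 in WT and -0.51 in the KO), Tmcc3 (-1.84; 1.72 and -0.13), Ppargc1b, a metabolic coactivator (-1.27; 1.28 and 0.02), Fzd7, a Wnt receptor (-4.32, 59095 bp away), Camsap1 (-2.91), Pitpnb (-2.34) and Plaat3 (-1.69). The region near Gbp6 did not pass, with a difference of -0.52 (adjusted p = 1.0; 4.67 and 4.14). All 3 larger responses were losses in WT cells. The Gbp5 region had -4.29 in WT and -0.30 in the KO (difference 3.99, SE 0.42, adjusted p = 0.00296; counts 217 to 11 in WT and 135 to 115 in the KO). Tgtp2 had -2.91 and 0.15 (difference 3.05, SE 0.36, adjusted p = 0.00464), and Acod1 -0.86 and 0.07 (difference 0.92, adjusted p = 0.0486).

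Some genes kept a gain in Irf1-KO cells, where 423 of 98476 regions were gained, with a median log2 change of 1.5, and 6 were lost, with a median of -1.09. Serpina3i, a protease inhibitor, gained 3.62 (SE 0.30, adjusted p = 0.000239), Ahrr, a repressor of the aryl hydrocarbon receptor, 4.02 (SE 0.41, adjusted p = 0.000548) and Gbp6 4.14 (SE 0.48). Slc44a3 rose from 2 to 73 counts, a ratio of 34.9 (95% interval 9.32 to 293.0), and a region 2228 bp from Tap2 from 3 to 61, a ratio of 19.4 (6.34 to 96.8). Of 117 regions at IFNγ and IRF1 targets, 24 rose and 2 fell, and 37 and 4 when adjusted over the list alone. Gbp4 gained 1.70, Cxcl9, a chemokine for T cells, 1.62, Gbp7 1.61, Tgtp1 1.52 and Socs1 1.15. Of 87 regions at type I interferon-stimulated genes, 2 rose (among them Zbp1 at 2.69), and 11 rose and 1 fell when adjusted over the list alone, while Ifit2 at 1.45 (adjusted p = 0.0729) and Ifit1 at 1.04 (adjusted p = 0.215) did not pass. Of 186 regions at NF-κB and inflammatory genes, 2 rose (Bcl3 1.42, and a region within Nfkb1 at 3:135639439-135640762 with 2.04 beside 1.58 in WT) and 1 fell (Nfkbia, -1.06), and 13 and 1 when adjusted over the list alone. Camera gave adjusted p = 1.59e-36, 1.16e-09 and 1.38e-05 for these lists, and adjusted p = 0.494, 0.459 and 0.633 with an estimated correlation. Abcg1 gained 1.49. Losses lay at Zyx (-1.51, SE 0.14, adjusted p = 0.000327), Irf1 itself (-1.12, SE 0.14), Tspoap1 (-0.95) and 68362 bp from Gm1966 (-2.11).

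Over 3145 WT-gained regions in the Irf1-KO fit, the median was 0.41 in the KO beside 1.2 in WT, and 359 were called gained (11.4%). The median difference was -0.93, and 91.3% of the 4106 WT-gained regions were negative, in part because they were chosen in the WT libraries. The 4106 regions ranked highest in WT pair 1 alone had a median of 1.06 in WT pair 2 and of 0.37 and 0.33 in the KO pairs. Medians of the difference over whole lists were -0.05 for type I interferon-stimulated genes (adjusted p = 0.776), with 3 of 95 regions smaller and 1 larger when adjusted over the list alone, -0.11 for IFNγ and IRF1 targets (adjusted p = 0.115), with 9 of 130 smaller and 2 larger when adjusted over the list alone, and 0.001 for NF-κB genes (adjusted p = 0.974). The count of smaller responses rested on single libraries, since it was 4 without Irf1-KO unstimulated library 1, 16 without either WT unstimulated library, 45 or 62 without WT IFNγ library 1 or 2, 55 without Irf1-KO unstimulated library 2 and 75 without Irf1-KO IFNγ library 2. The gains numbered 759 without Irf1-KO IFNγ library 2, 236 with DESeq2 and 3574 with the block, and the losses 32, 31 and 15 without IFNγ library 1, IFNγ library 2 and unstimulated library 1.

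Irf3-KO cells, which lack an inducer of IFNβ, were measured with LPS and with LPS and added IFNβ, with no replicates and so no test. Cmpk2, a nucleotide kinase, had 0.18 with LPS and 2.42 with IFNβ added, Iigp1 0.55 and 2.40, Usp18 0.20 and 1.67 and Nat10 -0.88 and 2.70. Ifit1 had 1.24 and 2.02. Nfkb1, by contrast, had 1.75 and 1.67, and Tnfaip3 1.02 and 1.13. Among regions with at least 50 counts, the highest ratios between both stimulated libraries lay at Nat10 (3.58; 4 and 91 counts), near Rcbtb1 (2.42), at Chn2 (2.27), Cmpk2 (2.24; 29 and 199 counts) and Ifi205, an interferon-inducible gene (2.18). The highest ratios to unstimulated cells were at Arhgef6 (3.49; 5 and 57 counts), near Peak1 (3.45) and at Prorp (3.15) with LPS, and at Anapc10 (3.52), Ifi205 (3.48; 6 and 90 counts) and Cog4 (3.44) with LPS and IFNβ.

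All 7166 WT-gained regions had a median log2 ratio of 0.60 with LPS and 0.80 with LPS and IFNβ in Irf3-KO cells. The 895 regions with a 2-fold gain in WT and under 0.5 times the WT change in Ifnar-KO cells had 0.52 and 1.03. The 2639 regions at 0.5 times or more had 1.09 and 1.18. The median ratio of the library with IFNβ to that with LPS alone was 0.52 in the former and 0.08 in the latter. It was 0.07 in 895 of the latter matched on the WT change, with WT medians of 1.51 and, in the former, 1.49. The medians of both sets lay above all of 10000 random sets of regions for each of these ratios.

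**Figure D4:**
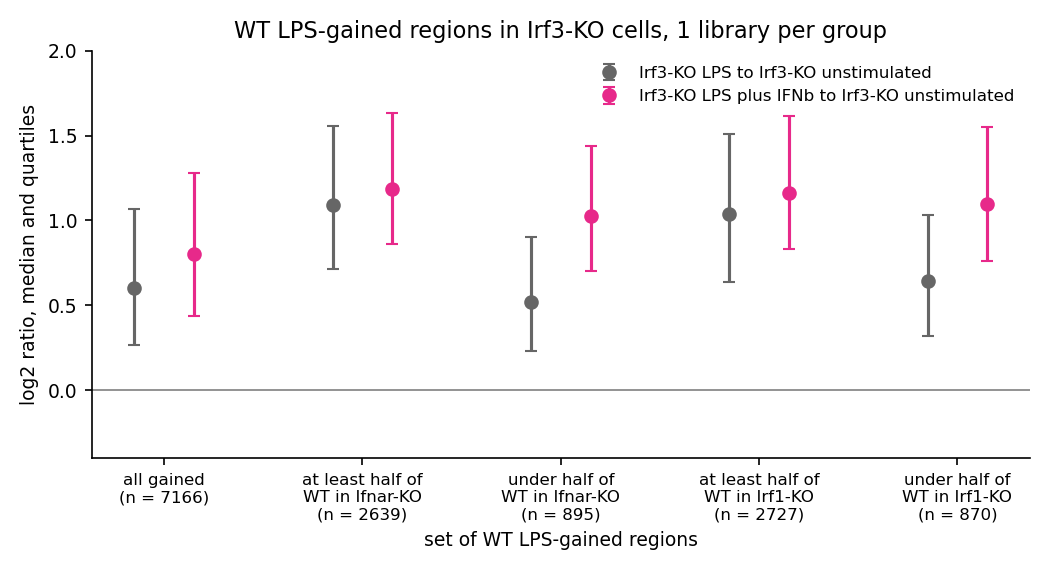
Log2 ratio to unstimulated cells of WT LPS-gained regions in Irf3-KO cells with LPS (grey) or LPS and IFNβ (pink), as medians (points) with quartiles (bars), for all gained regions and for those gained 2-fold in WT, split by their change in Ifnar-KO or Irf1-KO cells relative to WT. Regions at under 0.5 times the WT change in Ifnar-KO cells lie at 0.52 with LPS and at 1.03 with IFNβ added.

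A single IFNβ library of WT cells was compared with the unstimulated WT libraries. Among regions with at least 50 counts, Ifit1 had the highest log2 ratio (3.08; 210 counts against a mean of 24.3), followed by Cmpk2 (3.01; 164 against 25.3), a region 185092 bp from Olfr1324 (2.72; 96 against 76.3) and Gm4951 (2.60 and 2.55). Iigp1 had 2.53 (49 against 11.7), Zbp1 2.00 (94 against 18.3), Nat10 1.76 (41 against 6.3), Nos2 0.87 (273 against 295.3), Gbp3 0.70 (80 against 53.3) and Gbp7 0.66 (158 against 198.3). Gm6034, which fell with LPS, had -0.30 (71 against 167.7). Ratios are per base, so where the matched regions differ in length a ratio can be positive without a higher count. Of 60619 matched regions, 336 were counted as gained and 334, about as many, had a log2 ratio of -1 or lower. Of the 336, 204 were LPS-gained where independence gives 14.7, but both comparisons share the unstimulated libraries. With LPS calls from libraries 1 and 2 and the IFNβ library set against unstimulated library 3, 363 regions were counted as gained and 371 had a ratio of -1 or lower, and 188 of the 363 were LPS-gained where independence gives 6.1. The WT LPS-gained regions overlapped a region of the IFNβ table in 65.7% of cases (Clopper-Pearson 95% interval 64.6 to 66.8) beside 81.2% of unchanged regions matched on count and length. The median log2 ratio with IFNβ was 0.35 over 2645 matched LPS-gained regions and, with separate unstimulated libraries, 0.49 over 1023. Only LPS-gained regions with a counterpart among the regions of the IFNβ library could be matched, 2645 of 7166. This can favour regions that are high in that library, and separate unstimulated libraries do not remove it. The medians and overlaps therefore do not describe the LPS-gained regions as a whole. The IFNβ gains numbered 202 with a minimum of 50 counts and 1336 with an overlap of 1 bp.

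After LPS was washed out, regions called gained without the libraries of the course still lay above the unstimulated level at 6 days. In the time course, relative to unstimulated library 3, Ifit1 had 3.27 at 8 h and 4.03 at 6 days, Cmpk2 3.24 and 4.15, Ifit2 2.38 and 3.93, and Iigp1 3.48 and 3.88. Nat10 had 3.92 and 3.65. Nfkb1 had 2.41 and 1.38, and Tnfaip3 1.90 and 0.99. These are single named regions, and sets split by the response in Ifnar-KO cells both fell. The 197 regions with a smaller response there (replicate block) had medians of 1.58 at 8 h and 1.38 at 6 days. The 1686 regions gained there and not smaller had 1.47 and 1.17. Unstimulated library 3 and the 8 h library helped to call both sets. The Gbp5 region that fell with LPS had -4.52 at 8 h, -1.08 at 24 h, 0.53 at 72 h and 0.83 at 6 days. Over the 3243 regions called from WT libraries 1 and 2 alone the median was 1.47 at 8 h, 1.55 at 24 h, 1.35 at 48 h, 1.24 at 72 h, 1.21 at 96 h and 1.19 at 6 days. Over all 7166 gained regions it was 1.11 at 8 h and 0.92 at 6 days, where unstimulated library 3 and the 8 h library helped to call the regions. Of 6271 of these with an 8 h ratio above 0.5, 98.7% were above 0.5 times their 8 h value at 24 h and 79.8% at 6 days. Since every ratio shares unstimulated library 3, matched unchanged regions chosen in the same way also gave 66.4% and 60.2% of 128. Each time has 1 library and no unstimulated library of its own, so no test was made and a change with time in culture is not set apart. The highest ratio of 24 h to 8 h among regions with at least 50 counts lay at Uty on chromosome Y (4.04; 0 and 64 counts). Counts of 0 at 8 h and 64 at 24 h on chromosome Y speak against the same source of cells for these libraries, though at 1 region only. The source of the other course libraries is not known here. A change with time is therefore not set apart from a difference in the source of the cells either.

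**Figure D5:**
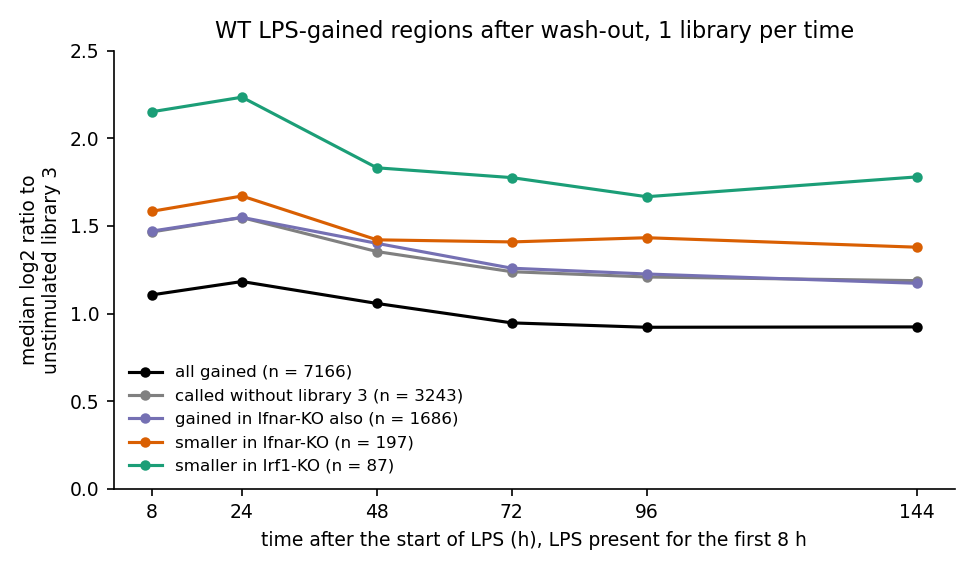
Median log2 ratio of WT LPS-gained regions to unstimulated library 3 against the time in hours after the start of 8 h of LPS, with 1 library per time, for all gained regions, for those called without library 3, and for subsets by their response in Ifnar-KO and Irf1-KO cells, the smaller ones taken with the replicate block. The grey line, of regions called without library 3, runs from 1.47 at 8 h to 1.19 at 6 days.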

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

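The test of how far reads in gained regions can lower the other regions, that of thinned WT pairs limited to those reaching 0.8 times the KO totals, that of a WT pair with lower totals than an Irf1-KO pair, and camera with an estimated correlation were chosen only after the result was seen. Without a replicate block, the genotype by stimulus tests showed a lower log2 change with LPS in Ifnar-KO than in WT cells at 2 regions and a higher one at 1. The latter, at Rsad2, was a loss in WT cells (-1.73) that was not called in the KO (0.49). With IFNγ the log2 change was lower in Irf1-KO than in WT cells at 125 regions and higher at 3. These 3, at Gbp5, Tgtp2 and Acod1, were losses in WT cells that were not called in the KO. With the replicate number as a block, the lower and higher counts were 206 and 41 for LPS in Ifnar-KO cells. For IFNγ in Irf1-KO cells they were 1386 and 142. With LPS, the preset-correlation test of gene lists showed a median difference from WT of -0.35 at type I interferon-stimulated genes in Ifnar-KO cells. At IFNγ and IRF1 targets it showed -0.20 in Ifnar-KO and -0.14 in Irf1-KO cells. None of the 3 list differences passed with an estimated correlation, at adjusted p = 0.494, 0.459 and 0.494 with an estimated correlation.

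Fewer regions were called gained after LPS in Ifnar-KO (1783) and Irf1-KO cells (1203) than in WT cells (7166). Fewer libraries and lower depth as the whole cause stay open. Over all choices of 2 WT pairs thinned to at most the KO totals, the lowest ratio to the KO count was 1.05. It came from choices in which WT pair 1 stood in for the deeper KO pair, at up to 6.54 M. Those choices stayed under the KO totals, but leaving them out was decided only after the result was seen. The other choices gave at least 1.79 times the KO count. They had 3187 to 4291 gained regions at the Ifnar-KO totals and 2895 to 4087 at the Irf1-KO totals. They argue against this cause only under that later restriction. Scatter between libraries stays open, since the gains numbered 870 and 3009 without the second and first unstimulated Ifnar-KO library, 143 and 1901 without the second and first unstimulated Irf1-KO library, 526 and 2007 without its second and first LPS library, and 4690 in WT without unstimulated library 3. A weaker response without interferon signalling or IRF1 stays open as well, where regions called from WT libraries 1 and 2 alone had medians of 1.48 in WT pair 3, 0.72 and 1.14 in the Ifnar-KO pairs and 0.57 and 1.21 in the Irf1-KO pairs.

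WT-gained regions changed less with IFNγ in Irf1-KO cells, with a median difference of -0.93, and regions ranked highest in 1 WT pair had medians of 1.061 or 0.884 in the other WT pair and at most 0.365 in the KO pairs. Lower depth is argued against, since the 1.061 came from WT pair 2, whose totals (12.1 and 14.0 M) were under those of Irf1-KO pair 1 (14.6 and 14.4 M) at 0.365, while thinning WT pairs to the Irf1-KO totals removed few reads and decides nothing (lowest median 1.351). Weaker enrichment in the Irf1-KO IFNγ libraries than in the unstimulated Irf1-KO libraries is argued against as well. Unchanged regions of the highest abundance decile differed from those of the lowest by -0.026 in their median difference (0.008 and 0.034). Weaker enrichment in all Irf1-KO libraries alike would not show in this test and stays open. Whether genotypes were handled on different days is not stated in the labels and stays open, as does any cause that acts on gained regions alone. A need for IRF1 at these regions is therefore a hypothesis, found and tested on the same libraries.

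LPS lowered 526 regions in WT cells. Scaling by the libraries' composition is argued against, since reads in gained regions rose from at least 4.87% to at most 9.08% of the total, which can lower the others by -0.065 on the log2 scale at most beside a median of -0.449. The planned test of neighbours came out as predicted beforehand for scaling, with no excess of gained neighbours. Of lost regions 6.1% had a gained region within 5 kb beside 7.1% of matched unchanged ones, a ratio of 0.86 (Fisher's exact test, two-sided p = 0.485). The argument against scaling thus rests only on the bound of -0.065, which was chosen after the result was seen. Of the 35 regions lost at least 2-fold, 11 (31.4%) had a gained region within 5 kb. These 35 were not matched or tested on their own. Loss at gene ends is argued against, since 11.6% of lost regions overlapped an end beside 18.0%, a ratio of 0.64 (Fisher's exact test, two-sided adjusted p = 0.00102). A change shared by all regions, which a spike-in would show, stays open, and a biological loss at these regions remains a hypothesis.

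The 6 WT libraries of the LPS comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 7166 gained and 526 lost regions and the highest of the other splits gave 0 of each, so that 1 of the 10 splits gave as many in both directions.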

How the results depend on the processing

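Tests of camera with an estimated correlation, of an overlap of 1 bp, of LPS against IFNγ without the shared library, of IFNβ against unstimulated library 3 alone and of medians without single KO libraries were chosen only after the result was seen. Of 5221 values of 506 named regions under the alternatives, 4913 were counted as the same, 173 lost the call and 135 gained one. Named regions that an alternative fit did not keep gave no value, so calls that ended in this way are not counted. The 4913 include any change of direction at regions that were not called in the report, which was not counted apart. Of 223 alternatives for the counts and medians, 124 stayed close to the value in the report and 99 moved by over 1.5 times or over their spread. No region called in the report and no median turned its direction under these alternatives. Counts and shares have no direction to turn.

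With a 2-fold minimum, WT LPS had 4180 gains and 35 losses, WT IFNγ 8 losses and Ifnar-KO LPS 4 losses. With the replicate number as a block, gains and losses were 10817 and 3770 in WT LPS, 8289 and 2416 in WT IFNγ, 6291 and 2207 in Ifnar-KO LPS, 5455 and 1887 in Irf1-KO LPS, and 3574 and 1228 in Irf1-KO IFNγ. By the sign of the difference from WT, the block gave 206 smaller and 41 larger LPS responses in Ifnar-KO, 87 and 1 in Irf1-KO, and 1386 and 142 for IFNγ. Libraries of the same number resembled each other in each comparison, with correlations of 0.248 to 0.471; with 2 libraries per group the other pairs take the opposite value by construction. DESeq2 gave 249 losses in WT LPS, 1985 gains and 15 losses in WT IFNγ, 746 and 3 in Ifnar-KO LPS, 279 and 2 in Irf1-KO LPS, and 236 gains in Irf1-KO IFNγ. Total counts gave 816 losses in WT LPS and 2 larger responses in Ifnar-KO, and a loess offset 77 losses in WT IFNγ.

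Leaving out 1 library gave 4690 to 7617 gains and 1.4e+02 to 716 losses in WT LPS, 2648 to 3813 and 26 to 267 in WT IFNγ, 870 to 3009 and 69 to 116 in Ifnar-KO LPS, 143 to 2007 and 2 to 80 in Irf1-KO LPS, and 414 to 759 and 8 to 32 in Irf1-KO IFNγ. It gave 0 to 3 smaller and 0 to 8 larger LPS responses in Ifnar-KO, 0 to 10 smaller in Irf1-KO, and 4 to 133 smaller for IFNγ. Where it left 1 library in a group, that library was assumed to vary like the others.

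WT-gained regions with a 2-fold minimum had KO medians of 1.29 (Ifnar-KO LPS), 1.23 (Irf1-KO LPS) and 0.49 (Irf1-KO IFNγ), and the last ran from 0.35 to 0.49 without single KO libraries. The IFNβ gains numbered 202 with at least 50 counts 1336 with an overlap of 1 bp and 363 against unstimulated library 3 alone. In Irf3-KO cells the LPS median was 0.62 with total counts and 0.56 with a prior count of 5, that of LPS with IFNβ 0.75 with a prior count of 5, and their ratio 0.11 with total counts. At 6 days the share above 0.5 times the 8 h value was 83.8% with total counts and 87.3% with a 2-fold minimum, and the median 0.98 with total counts, 0.88 with a prior count of 5 and 1.42 with a 2-fold minimum. Gene lists passing camera numbered 20 of 96 with the preset correlation and 0 with an estimated one, where 20 kb gave 22. A 2-fold or count minimum removes regions by construction, a prior count shrinks ratios, and fewer libraries give fewer degrees of freedom; for the other moves the cause was not tested. The motif alternatives could not be run without a genome, and an overlap of 1 bp has no meaning where tables share their regions. In simulated data at this depth, 2-fold changes were found in 38% to 77% of regions in single responses and in 27% to 35% in differences from WT, so many changes of this size can be missed. Changes at regions below 1 CPM in unstimulated cells were not simulated.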

Other observations

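Regions lost in WT cells with LPS mostly lay below 0 in both KO responses too. The 526 lost regions had medians of -0.30 in Ifnar-KO and -0.34 in Irf1-KO cells with LPS, and 94.0% and 96.7% of them were below 0. The 35 regions lost at least 2-fold had -1.47 in WT, -0.27 in Ifnar-KO and -0.95 in Irf1-KO cells. In Irf3-KO cells the 526 had -0.18 both with LPS and with IFNβ added, and the 35 had -0.43 and -0.99. The Gbp5 region among them had -4.10 in WT, -0.85 in Ifnar-KO, -3.45 in Irf1-KO, and -1.03 and -2.78 in Irf3-KO cells without and with IFNβ. Vcpip1 had -2.35, -0.10, -1.76, -0.31 and -1.77 in the same order, and Gm6034 -2.33, 0.14, -2.27, -0.82 and -1.81. Without a block the difference from WT in Ifnar-KO cells was not called at Gm6034 (2.46, edgeR adjusted p = 0.11), and with the replicate number as a block it was called there and at these Gbp5 and Vcpip1 regions.

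With the replicate number as a block, 206 regions had a lower log2 change with LPS in Ifnar-KO than in WT cells, of which 197 were gained in WT. In Irf1-KO cells 87 regions had a lower one. The 197 had medians of 1.65 in WT, 0.06 in Ifnar-KO and 0.89 in Irf1-KO cells. The 87 had 2.20, 1.30 and 0.06. In Irf3-KO cells the 197 had 0.36 with LPS and 1.12 with IFNβ added, and the 87 had 0.68 and 1.36. Subsets were defined after seeing the data, and the sets come from the WT and KO libraries that they are measured in.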
